A study of Danio rerio with 17 samples.

How the data were processed

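Gene expression was measured in pooled brains of adult zebrafish of the AB strain that received domoic acid (DA), an excitatory amino acid toxin made by marine diatoms that acts on ionotropic glutamate receptors. The dose was 1.1 µg per g of fish, injected into the body cavity, and controls received the buffer vehicle alone. The labels call this dose symptomatic, since fish showed abnormal swimming soon after injection and then recovered. Brains were collected 24, 48 or 168 h after injection, and each RNA replicate was a pool of 3 to 4 brains. The 17 samples fall into 6 groups of treatment and time, with 3 arrays in each group except the 48 h controls, which have 2. Replicate numbers were not taken as pairs.

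Total RNA was labelled with biotin and hybridised to the Affymetrix Zebrafish Genome array, a 1-colour array on which most genes are read near their 3′ end. The deposited values are on the log2 scale, with 1 value per probe set and array, as processed by the authors. The submitters' processing notes name oligo, RMA and limma, and versions are not given in the sources used here. RMA corrects the background, makes the distribution of probe values alike between arrays and summarises the probes of a probe set. A change shared by most transcripts of an array is therefore removed before the values are compared. The values ran from 3.65 to 15.0, and array medians ran from 6.11 to 6.23. Arrays give no count of molecules, so the number of arrays limits the precision.

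The table holds 15617 probe sets, of which 115 are control probe sets of the manufacturer. These were used for array quality alone, and 15502 were tested with no filter on level. Symbols came from the platform annotation and were brought up to date through the Entrez gene number, which was found for 10711 of the 10795 probe sets with 1 symbol. A further 135 probe sets carried several symbols and 4572 carried none. Where a gene had several probe sets, the probe set with the highest mean over all arrays stood for it, which left 8793 genes. Probe sets with the suffix _x_at or _s_at, which can bind related transcripts, numbered 471.

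All arrays were fitted together with limma 3.58.1 in R 4.3.3, with 1 mean per group, so that the groups shared an estimate of the spread. Moderated two-sided tests compared DA with control at each time. The same fit gave the mean of the 3 effects, the difference of the effect between times as a moderated F test with its pairwise differences, and time among the controls as an F test. Values were adjusted by Benjamini-Hochberg over all probe sets tested, at an adjusted p under 0.05. The fit had 11 residual degrees of freedom and 4.39 prior degrees of freedom, and the median residual SD was 0.16 on the log2 scale. The median standard error (SE) of a change was 0.13 at 24 h and 0.15 at 48 h.

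Gene lists were tested with camera in limma at a preset correlation of 0.01, over 33 lists with at least 5 measured genes. Each p was adjusted over the lists within a contrast. Camera with an estimated correlation and fry, which tests each list by itself, stand beside it. No list passed with an estimated correlation or with fry in any of the 4 DA contrasts, so every list call in these 4 contrasts depends on the preset correlation. The list of metabotropic glutamate receptors had too few measured genes and was not tested. Agreement between times was measured as the correlation of changes across probe sets, with 100 relabellings of treatment within each time.

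The comparisons, the tests, the lists, the rule for naming genes and most alternatives were written before the data were examined. For each DA contrast, the rule named up to 12 genes per direction among those that passed with every DA array on one side of every control array. If fewer than 5 passed, the 5 genes per direction with the smallest unadjusted p were named as well. For each list that passed, up to 4 members with the smallest p in its direction were named, and 10 measured genes chosen for their part in excitotoxicity or brain injury were always given. Applying this rule to the 24 h comparison without DA replicate 1 was chosen after seeing the data.

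The alternatives were median centring, repeated quantile normalisation, cyclic loess, filters on dim probe sets, an intensity trend with robust variances, array weights, the replicate number as a block, other thresholds, fits with fewer groups, an additive model and leaving out each array in turn. For lists they were an estimated correlation, ranks, fry and the mean over the probe sets of a gene. Added after seeing the data were the removal of both doubted 24 h arrays, and the level of the hybridisation spike-ins, the GAPDH 3′ to 5′ difference and the level of blank probe sets as covariates. Also added then were array weights for lists, the removal of each array from the control time test and from the correlations, and list tests on differences between times and on time in controls. The procedure was tested on simulated data. With 50 probe sets changed per size at 24 h, 44% of changes of 0.5 on the log2 scale and 96% of changes of 1 were recovered, with 15 false calls over all sizes. At 48 h, 26% of changes of 0.5 and 90% of changes of 1 were recovered. With no change at 168 h no probe set was called. A list shifted by 0.2 among the 8793 genes was found, with 0 other lists called. Every simulated array had the same spread, without an array that stood apart as DA replicate 1 did at 24 h. The shares recovered are therefore no measure of the real 24 h comparison. There, with all arrays, chd2 was at -1.61 with an adjusted p of 0.108 in limma. The simulated genes also varied independently, so the list result does not show how list calls behave under correlation between genes. In the real data the estimated correlation was 0.25 for proteasome subunits, the list shifted here, and 0.40 for ribosomal proteins.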

Results

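The 17 arrays described brains of adult zebrafish 24, 48 and 168 h after an injection of domoic acid or vehicle. Each time had its own controls, with 3 DA arrays and 3 control arrays at 24 h and at 168 h, and 3 DA arrays and 2 control arrays at 48 h. Pearson correlations between arrays across probe sets ran from 0.970 to 0.997. The array of DA replicate 1 at 24 h stood apart. Its 17 blank tag probe sets, which match no zebrafish transcript, averaged 5.74 on the log2 scale against 4.94 to 5.18 on the 16 other arrays. Its median correlation with the other arrays was 0.976. Control replicate 3 at 24 h had a GAPDH 3′ minus 5′ difference of 4.63 against at most 3.70 elsewhere, a sign of shorter labelled RNA. Spike-ins added at hybridisation averaged 10.39 to 10.96 on the 24 h control arrays, 10.56 on DA replicate 1 at 24 h and 9.79 on DA replicates 2 and 3 at 24 h. At 48 h they averaged 10.8 on control replicate 1, 9.70 on control replicate 2 and at most 9.40 on the DA arrays.

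**Figure D1:**
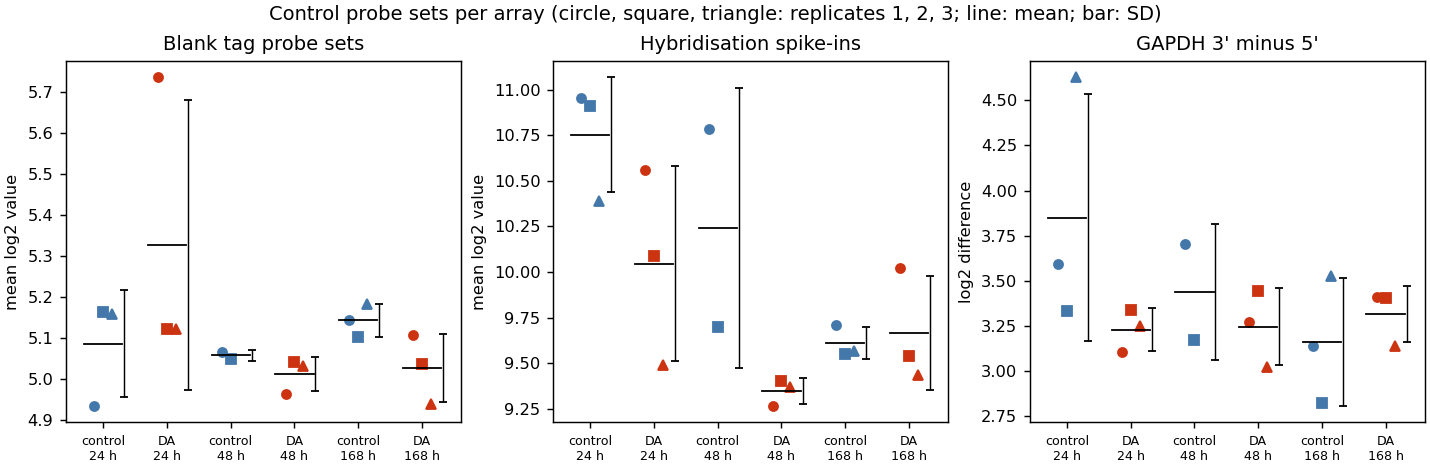
Mean log2 level of the blank tag probe sets, mean log2 level of the hybridisation spike-ins, and GAPDH 3′ minus 5′ log2 difference, for each array by group. Points are arrays, lines are group means and bars are SD. The blank level of 5.74 belongs to DA replicate 1 at 24 h and the GAPDH difference of 4.63 to control replicate 3 at 24 h.

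The first comparison asked which transcripts differed 1 day after the toxin, when the swimming signs were past. A probe set of add3a, which encodes an adducin of the membrane skeleton, fell from 8.27 ± 0.28 (SD, n = 3) in controls to 6.94 ± 0.14 (SD, n = 3) in DA brains, which is 2.51-fold lower (adjusted p = 0.0248, limma). The other 2 probe sets of add3a were at -0.54 (adjusted p = 0.572) and 0.35 (adjusted p = 0.301) on the log2 scale. cyp2p10, a cytochrome P450 of the family that oxidises fatty acids and foreign compounds, fell from 6.59 ± 0.21 (SD, n = 3) to 5.75 ± 0.11 (SD, n = 3), 1.79-fold lower (adjusted p = 0.0270). Of the 15502 probe sets tested at 24 h, 5 passed, all lower in DA. The other 3 carried no symbol and were 2.25-fold (adjusted p = 0.0497), 2.02-fold (adjusted p = 0.0497) and 1.70-fold (adjusted p = 0.0248) lower. At an unadjusted p under 0.05 there were 2084 probe sets, 858 higher and 1226 lower, where chance alone would give about 775.1. cyp2p10 was named by the rule, and the other 4 were named after their values were seen. Next in order of p, and short of the threshold, ica1, a protein of secretory vesicles, was at -1.31 and the LIM homeobox gene lhx9 at -0.67, with tmem256 at -0.50 and the stanniocalcin stc2a at -0.88 (adjusted p = 0.0684 for each). On the higher side ppp2r2ab, a subunit of protein phosphatase 2A, was at 0.54 (adjusted p = 0.0776) and the ubiquitin ligase mgrn1a at 0.84 (adjusted p = 0.0952). The kinase dstyk at 0.42, the export receptor xpo6 at 0.63 and the deubiquitinase relative cyldl at 0.38 each had an adjusted p of 0.116. The count of 5 at 24 h was 0 with the spike-in level or the GAPDH difference as a covariate. It was also 0 with the 2 groups alone and with the replicate number as a block. With the blank level as a covariate and with array weights it rose, as given below, and it was sensitive to the arrays used. It was 217 without DA 24 h replicate 1, 38 without control 24 h replicate 2, 82 without DA 168 h replicate 1 and 8 without control 168 h replicate 2. It was 2 without control 168 h replicate 1, and 3 without either control array at 48 h, DA 168 h replicate 2 or DA 168 h replicate 3. It was 0 without control 24 h replicate 1 or 3, DA 24 h replicate 2 or 3, or any DA array at 48 h.

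Without DA 24 h replicate 1, the 24 h comparison set 2 DA arrays against 3 control arrays, a choice made after seeing that array's blank probe sets and its effect on the count. The chromatin remodelling ATPase chd2 fell from 9.53 ± 0.33 (SD, n = 3) to 7.52 ± 0.16 (SD, n = 2), 4.03-fold lower (adjusted p = 0.0141, limma). The histone demethylase kdm4b was 3.19-fold, the Paf1 complex member rtf1 3.11-fold, the remodelling ATPase atrx 2.99-fold and the remodelling factor rsf1b.1 2.73-fold lower. The calcium pump atp2b4 was 3.20-fold (adjusted p = 0.0304), the neurofilament gene neff1 3.09-fold (adjusted p = 0.0141) and the adhesion gene cadm3 3.06-fold lower. The remaining named falls were ube2ql1 at -1.55, ankrd12 at -1.53, si:ch211-250g4.3 at -1.47 and ica1 at -1.41. The co-chaperone fkbp5, a glucocorticoid target, rose from 8.01 ± 0.72 (SD, n = 3) to 9.96 ± 0.55 (SD, n = 2), 3.85-fold higher (adjusted p = 0.0271). The RNA-binding gene tial1 rose 2.30-fold (adjusted p = 0.00798), the ubiquitin ligase siah1 2.13-fold and the splicing genes sfswap 1.98-fold and u2surp 1.80-fold. fam107b rose by 1.14 on the log2 scale, eif4g2b by 0.97, mgrn1a by 0.96, nucb1 by 0.87 (an _s_at probe set), akirin2 by 0.86, LOC567909 by 0.85 and sppl2 by 0.84. In all 217 probe sets passed, 96 higher and 121 lower. Those with a single symbol named 133 genes, 62 higher and 71 lower. All 5 probe sets that passed with all arrays were among them. On DA replicate 1 itself, 53 of the 217 (24.4%) lay nearer to the other DA arrays than to the controls, and fkbp5 was at 8.35. For 54 of the 217 it lay within the range of the controls. With each probe set centred over all arrays, the 121 that fell averaged -0.03 on DA replicate 1. They averaged 0.38 to 0.46 on the controls, and -0.55 and -0.57 on DA replicates 2 and 3. The 96 that rose averaged -0.44 on DA replicate 1, -0.37 to -0.27 on the controls and 0.39 on both other DA arrays. The 24 h control arrays carried the higher spike-in levels given above. With the spike-in level as a covariate 3 probe sets passed. The 217 then had a median size of change of 0.71 against 0.75 and a median SE of 0.21 against 0.15.

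**Figure D2:**
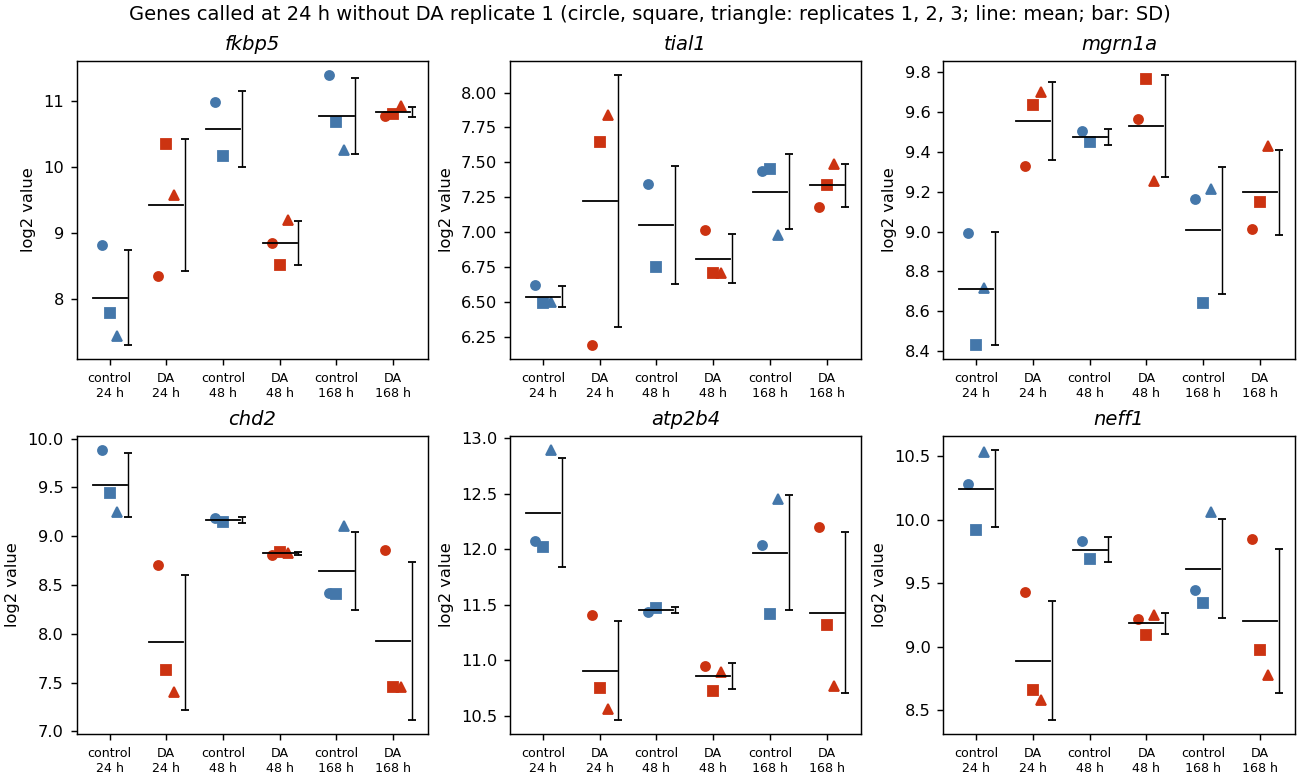
Log2 values per array of fkbp5, tial1, mgrn1a, chd2, atp2b4 and neff1 in the 6 groups. Points are arrays with the shape giving the replicate, lines are group means and bars are SD. At 24 h, DA replicate 1 lies at 8.35 for fkbp5, near the control mean of 8.01, while the mean of DA replicates 2 and 3 is 9.96.

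At 24 h, 3 gene lists passed. Of 71 cytosolic ribosomal protein genes, 52 were lower in DA, with a median of -0.12 on the log2 scale (adjusted p = 0.000213, and adjusted p = 0.954 with an estimated correlation). Examples were rps29 at -0.58, rpl39 at -0.60, rpl38 at -0.44 and rpl29 at -0.54. Of 84 genes of mitochondrial oxidative phosphorylation, 61 were lower, with a median of -0.11 (adjusted p = 0.000213, and adjusted p = 0.954 with an estimated correlation). Here uqcrq was at -0.54, ndufa5 at -0.49, ndufa6 at -0.44 and ndufb2 at -0.68. Over all probe sets none of these members passed in limma, while 17 and 13 were lower at an unadjusted p under 0.05. Adjusted over the list alone, 4 ribosomal and 6 oxidative phosphorylation genes did, all lower. Both calls were lost without control 24 h replicate 1 (adjusted p = 0.105 and 0.132) and without DA 24 h replicate 3 (0.216 for both), and with the spike-in level as a covariate (0.236 and 0.159). In controls both lists were also lower at 168 h than at 24 h, with medians of -0.16 and -0.09. Over all DA arrays the medians between these times were -0.00 and 0.03. The 24 h difference may thus lie in the 24 h controls. Without DA 24 h replicate 1, oxidative phosphorylation was higher at 168 h than at 24 h in DA fish, so a part may lie there. Neither was tested. Markers of retina, lens and pineal, tissues next to the brain or of it, were higher in 35 of 40 genes, with a median of 0.17 (adjusted p = 0.0144, and adjusted p = 0.954 with an estimated correlation). rpe65a was 2.01-fold higher, opn1sw1 at 0.62, aanat2 at 0.36 and guca1c at 0.73, and adjusted over the list alone 0 passed in limma, against 3 higher and 2 lower at an unadjusted p under 0.05. That call rested on DA 24 h replicate 1, the array with bright blank probe sets. Without it the median was -0.05 and the adjusted p 0.344, and without control 24 h replicate 1 the adjusted p was 0.166. Without DA 24 h replicate 1, oxidative phosphorylation (adjusted p = 1.18e-07), ribosomal proteins (8.16e-06) and skeletal muscle and skin markers (0.0241) passed, all lower and each with an adjusted p of 0.886 with an estimated correlation. The number of lists was 0 without control 24 h replicate 1 and 5 without control 24 h replicate 2.

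**Figure D3:**
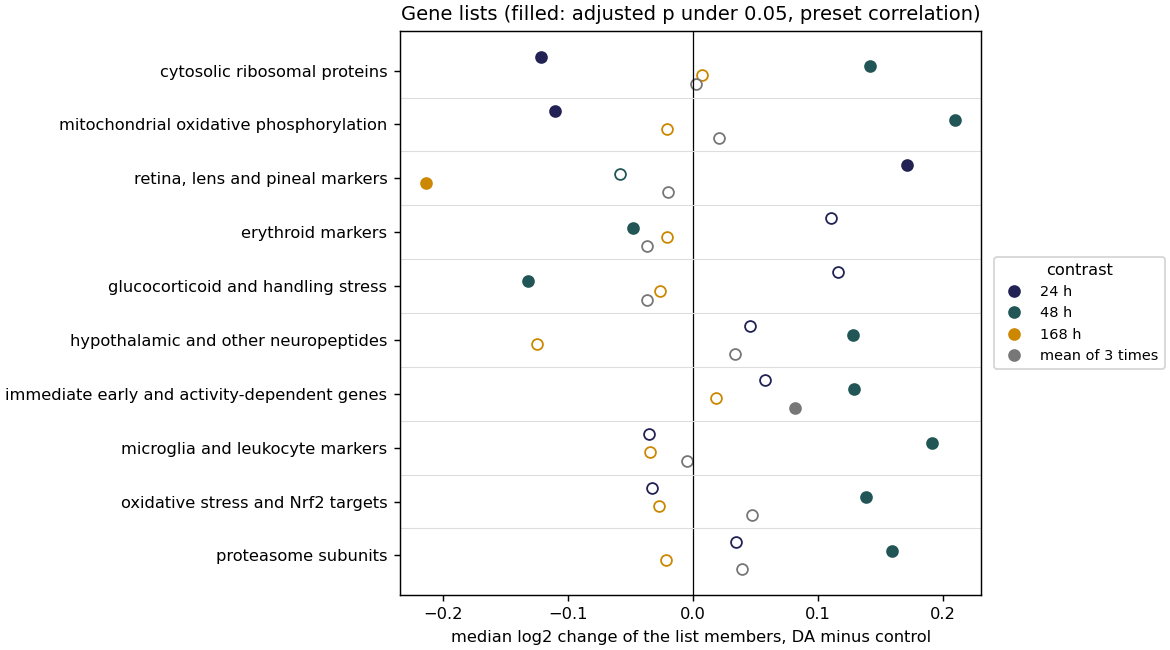
Median log2 change, DA minus control, of the members of each of the 10 lists that passed in at least 1 contrast, at 24, 48 and 168 h and for the mean of the 3 times. Filled points passed at an adjusted p under 0.05 with the preset correlation, and none did with an estimated correlation. The oxidative phosphorylation list lies at -0.11 at 24 h and at 0.21 at 48 h.

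At 48 h, immediate early genes, which neurons switch on with activity, were higher in DA brains as a group. Of 36 members 24 were higher, with a median of 0.13 (adjusted p = 0.000514, and adjusted p = 0.464 with an estimated correlation). fosab was at 8.68 ± 0.34 (SD, n = 3) in DA against 7.59 ± 0.78 (SD, n = 2) in controls, 2.13-fold higher (adjusted p = 0.726, limma). Much of this gap came from control 48 h replicate 1, at 7.04. Control 48 h replicate 2 was at 8.14, and the 24 h and 168 h controls were at 8.15 to 8.70. junbb was at 0.72, nr4a1 at 0.75 and ier5 at 0.49 on the log2 scale. Adjusted over the list alone, 2 members passed, both higher. Genes of the glucocorticoid and handling stress list, called glucocorticoid-responsive for short, were lower in 12 of 20 members. Their median was -0.13 (adjusted p = 0.00702, and adjusted p = 0.234 with an estimated correlation). As written, the list also names stress peptides and steroid receptors, so it is not limited to genes that respond to glucocorticoid. fkbp5 was at 8.85 ± 0.33 (SD, n = 3) against 10.57 ± 0.58 (SD, n = 2), a log2 change of -1.72 (adjusted p = 0.763), hsd11b2, which inactivates cortisol, at -0.77, klf9 at -1.01 and igfbp1a at -0.47. igfbp1a is also among the genes that prompted the oxygen-responsive list below. Adjusted over the list alone, 2 members of the glucocorticoid and handling stress list passed, both lower.

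Genes of oxidative phosphorylation were higher at 48 h in 80 of 84, with a median of 0.21 (adjusted p = 7.23e-11, and adjusted p = 0.495 with an estimated correlation). ndufa4a was at 0.45, sdhc at 0.35, ndufa13 at 0.33 and atp5l at 0.38, while the single member to pass adjusted over the list alone, cox4i1l, was at -0.84. Ribosomal protein genes were higher in 60 of 71, with a median of 0.14 (adjusted p = 2.63e-05, and adjusted p = 0.633 with an estimated correlation), such as rps23 at 0.41, rps10 at 0.30, rps16 at 0.29 and rpl23 at 0.27. Proteasome subunits were higher in 31 of 42, with a median of 0.16 (adjusted p = 0.00254, and adjusted p = 0.581 with an estimated correlation), such as psmd13 at 0.46, psmb6 at 0.35, psmc2 at 0.34 and psmd5 at 0.24. Oxidative stress genes and Nrf2 targets were higher in 24 of 29, with a median of 0.14 (adjusted p = 0.0102, and adjusted p = 0.464 with an estimated correlation), such as the reductases txnrd3 at 0.44 and gsr at 0.26, pgd at 0.31 and the ferritin gene fthl27 at 0.26. Genes of the neuropeptide list were higher in 16 of 19, with a median of 0.13 (adjusted p = 0.0102, and adjusted p = 0.234 with an estimated correlation), among them gnrh3 at 0.53 and gnrh2 at 0.43 (both _s_at probe sets), adcyap1b at 0.19 and tph2, a member that encodes an enzyme of serotonin synthesis and no neuropeptide, at 0.35. Microglia and leukocyte markers were higher in 16 of 23, with a median of 0.19 (adjusted p = 0.0160, and adjusted p = 0.464 with an estimated correlation), led by lcp1 at 0.63 and lyz at 0.62, with lgals9l1 at 0.40 and cd74b at 0.27. Erythroid markers were lower in 12 of 17, with a median of -0.05 (adjusted p = 0.0376, and adjusted p = 0.464 with an estimated correlation), with nt5c2l1 at -0.90, slc4a1a at -0.59, epb41b at -0.29 and sptb at -0.25. Of these 7 lists, cox4i1l alone passed adjusted over the list alone. With either control array at 48 h left out, a lone control array, assumed to vary like the other groups, stands against the 3 DA arrays. Most of these calls were lost without control 48 h replicate 1, whose spike-in level of 10.8 is given above. Without it 2 of the 9 lists passed, immediate early genes and proteasome (adjusted p = 0.0138 for both), while oxidative phosphorylation, glucocorticoid-responsive and erythroid genes were each at 0.0665. The others were then at 0.999 (ribosomal proteins), 0.326 (oxidative stress) and 0.264 (neuropeptides, and microglia and leukocytes). The microglia and leukocyte call was also lost without DA 48 h replicate 2 (0.166), and the erythroid call without control 24 h replicate 3 (0.0521), control 48 h replicate 2 (0.197), DA 48 h replicate 1 (0.143) or DA 48 h replicate 2 (0.154). With the spike-in level as a covariate the adjusted p was 0.811 for erythroid markers, 0.151 for neuropeptides, 0.271 for microglia and leukocytes and 0.158 for oxidative stress. Among probe sets above the median level, erythroid (0.305), microglia and leukocyte (0.147) and oxidative stress genes (0.0779) did not pass. On ranks the erythroid (0.169) and glucocorticoid-responsive lists (0.107) did not, nor did erythroid markers with the blank level as a covariate (0.0522).

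No single probe set passed at 48 h in limma, while 734 had an unadjusted p under 0.05, 405 higher and 329 lower, where chance would give about 775.1. The count was 4 without control 48 h replicate 2, where the lone control array is assumed to vary like the other groups. Closest to the threshold were the cytochrome oxidase isoform cox4i1l at -0.84 and the prolyl hydroxylase egln3 at -0.92 (adjusted p = 0.335 for both), both known to respond to oxygen. klf2b was at -0.56 (adjusted p = 0.340), tns1b at -0.48 (adjusted p = 0.501) and cul5b at -0.96 (adjusted p = 0.529). On the higher side were hadhb at 0.60 and cpt1ab at 0.85, both of mitochondrial fatty acid oxidation, the amino acid transporter slc1a4 at 0.74, bzw2 at 0.69 and blcap at 0.61 (adjusted p = 0.396 to 0.529).

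**Figure D4:**
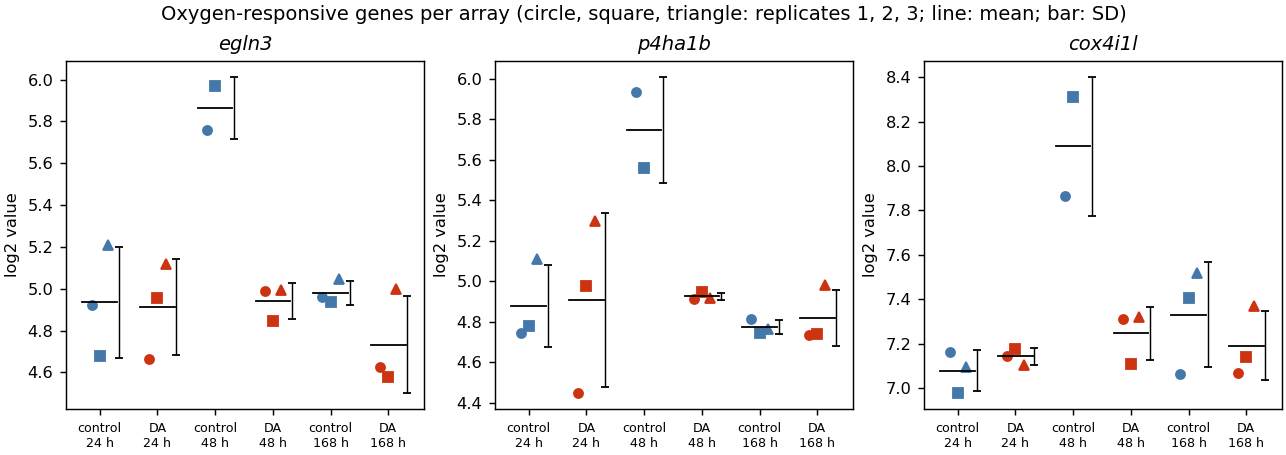
Log2 values per array of egln3, p4ha1b and cox4i1l, genes known to respond to oxygen, in the 6 groups. Points are arrays with the shape giving the replicate, lines are group means and bars are SD. The 48 h controls lie at 5.76 and 5.97 for egln3, above the 15 other arrays.

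At 168 h the question was what remained after 1 week. Markers of retina, lens and pineal were lower in DA in 40 of 40 genes, with a median of -0.21 (adjusted p = 4.62e-08, and adjusted p = 0.877 with an estimated correlation). The isomerase rpe65a was at 6.88 ± 0.56 (SD, n = 3) against 7.94 ± 0.11 (SD, n = 3), 2.09-fold lower (adjusted p = 0.999, limma). The transducin genes gngt1 and gnat1 were at -1.15 and -0.35 and the opsin opn1mw2 at -0.35, with gngt1 at -0.47 without control 168 h replicate 3. Adjusted over the list alone 0 passed, with 2 lower at an unadjusted p under 0.05. The blank tag probe sets were also lower in DA at 168 h, with a difference of -0.12, and with the blank level as a covariate the list had a median of -0.08 (median SE 0.13 against 0.17) and an adjusted p of 0.234. No probe set passed at 168 h in limma, while 468 had an unadjusted p under 0.05, 188 higher and 280 lower. Those with the smallest p were vps52 at -0.65, trim71 at -0.65, f13a1a.1 at -0.43, the retinol carrier rbp4 at -0.58 and fcho2 at -0.47 on the lower side. On the higher side were sec24b at 0.33, dynll2b at 0.36, nck2b at 0.32, the adhesion gene cntn1b at 0.56 and ddx3xa at 0.28 (adjusted p = 0.999 for each). The number of lists was 3 without control 168 h replicate 1, 2 without control 168 h replicate 3, 3 without DA 168 h replicate 1, 4 without DA 168 h replicate 2 and 3 without DA 168 h replicate 3.

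**Figure D5:**
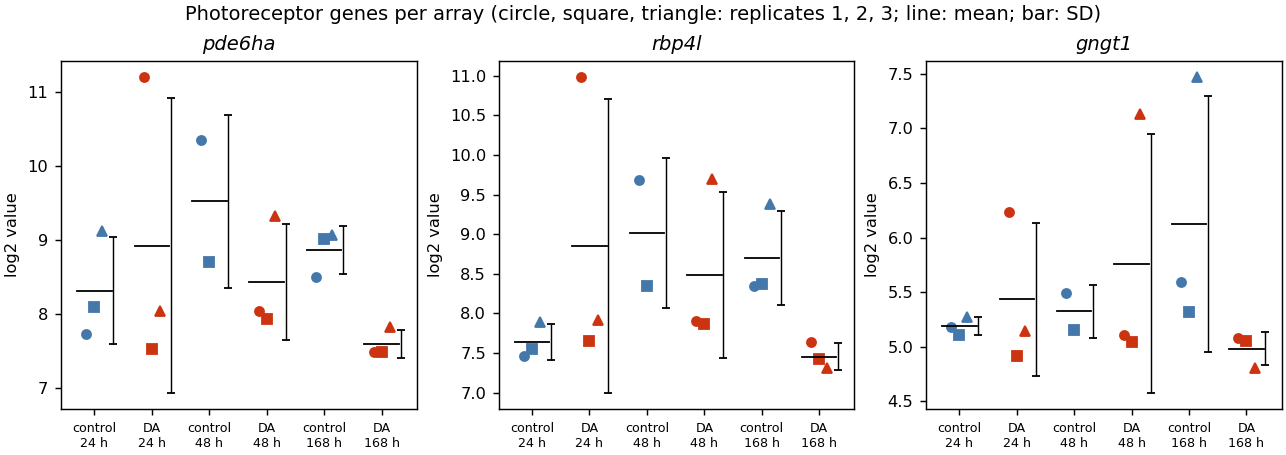
Log2 values per array of the photoreceptor genes pde6ha, rbp4l and gngt1 in the 6 groups. Points are arrays with the shape giving the replicate, lines are group means and bars are SD. DA replicate 1 at 24 h is highest for pde6ha, at 11.20, and gngt1 is highest on control replicate 3 at 168 h, at 7.47.

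Averaged over the 3 times, immediate early genes were higher in DA in 27 of 36 members, with a median of 0.08 (adjusted p = 0.00317, and adjusted p = 0.963 with an estimated correlation). junbb was at 0.39, npas4a at 0.48 (adjusted p = 0.359, limma), btg2 at 0.32 and egr2b at 0.18, and adjusted over the list alone 1 passed. The call was lost without both doubted 24 h arrays (adjusted p = 0.163) and with the GAPDH difference as a covariate (0.0748). The number of lists passing was 5 without control 24 h replicate 1 or control 48 h replicate 2, and 4 without DA 24 h replicate 1 or DA 48 h replicate 3. It was 2 without DA 24 h replicate 3, control 48 h replicate 1, control 168 h replicate 1, control 168 h replicate 2 or DA 168 h replicate 1. No single probe set passed in limma, while 1191 had an unadjusted p under 0.05, 375 higher and 816 lower. The vesicle gene ica1 was at -0.86 and the protein kinase C gene prkcea at -0.49 (adjusted p = 0.0588 for both). hic1l was at -0.33, cyp2p10 at -0.42 and vps52, which tethers vesicles to the Golgi, at -0.54 (adjusted p = 0.0647 to 0.0678). On the higher side were ints14, nck2b and ift52 (adjusted p = 0.110 for each), gdi2 (0.114) and blcap (0.136), from 0.21 to 0.28. The count was 163 without DA 168 h replicate 1, of which 159 were lower, and 64 without DA 24 h replicate 1. It was 5 without control 24 h replicate 2 or control 168 h replicate 2, and 1 without control 24 h replicate 3 or control 48 h replicate 2.

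Of the genes given whatever their values, none passed at any time or in the mean. npas4a, an activity-dependent transcription factor, was at 0.61 at 24 h, 0.64 at 48 h and 0.19 at 168 h. egr1 was at 0.32, 0.59 and -0.13 and fosab at -0.10, 1.09 and 0.02 at these times. The AMPA receptor genes gria2a and gria2b were at 0.04 and 0.01 in the mean, the NMDA receptor gene grin1a at 0.04, bdnf at 0.13 and the glutamate transporter slc1a2b at -0.00. gfap, a marker of radial glia, was at 0.07 and the brain aromatase cyp19a1b at 0.01. il1b, hsp70l, grin1b and hmox1a were not measured under these symbols. Ionotropic glutamate receptors as a list had a lowest adjusted p of 0.410, at 48 h, and GABA genes 0.388, at 48 h.

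The remaining lists did not pass in any of the 4 contrasts, and their lowest adjusted p were as follows. Voltage-gated ion channels reached 0.0547 in the mean, lower, and cell cycle genes 0.0573 at 24 h, higher. Skeletal muscle and skin markers reached 0.0912 at 168 h, circadian clock genes 0.106 at 48 h, estrogen-responsive genes 0.208 at 24 h and the unfolded protein response 0.219 at 48 h. Sterol synthesis and synaptic vesicle genes each reached 0.227 at 168 h, endothelial markers 0.244 in the mean, liver and gonad markers 0.275 at 168 h, apoptosis genes 0.281 at 168 h and glycolysis 0.300 at 168 h. Oligodendrocyte and myelin markers reached 0.410 at 48 h, interferon genes 0.475 at 168 h, astroglia and radial glia markers 0.531 at 48 h and glutamate uptake genes 0.567 in the mean. Calmodulin and calcium-dependent kinases reached 0.593 at 48 h, heat shock genes 0.604 at 24 h, cytokines and acute phase genes 0.664 at 48 h, neurogenesis genes 0.736 at 48 h and pituitary hormones 0.773 at 168 h. Among the 14 passing results, the median, the mean and the test had the same sign. Among the 118 others, the median and the test differed in sign in 23.

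Whether the DA effect differed between times was tested directly. Oxidative phosphorylation went from a median of -0.11 at 24 h to 0.21 at 48 h, and this difference passed (adjusted p = 5.80e-14, and adjusted p = 0.429 with an estimated correlation). Ribosomal protein genes went from -0.12 to 0.14 (adjusted p = 6.86e-10, and adjusted p = 0.50 with an estimated correlation). With each array left out the adjusted p ran up to 1.72e-06 for oxidative phosphorylation and 0.00192 for ribosomal proteins, both without control 48 h replicate 1, where the median differences were 0.18 against 0.33 and 0.13 against 0.28. The value of either list at 24 h or at 48 h alone rested on single arrays, as given above. Retina, lens and pineal markers went from 0.17 at 24 h to -0.21 at 168 h (adjusted p = 4.45e-07, and adjusted p = 0.843 with an estimated correlation). This call rested on DA 24 h replicate 1, without which the 24 h median was -0.05, lower at both times, and the adjusted p of the difference 0.0821. With the blank level as a covariate it was 0.725. These list tests were added after seeing the data. For single probe sets, 0 passed the F test in limma, with 971 at an unadjusted p under 0.05. The pairwise differences gave 0 as well, with 1002 (48 h against 24 h), 1344 (168 h against 24 h) and 481 (168 h against 48 h) at that level. Across probe sets, the changes at 24 and 48 h correlated with r = 0.17 and rho = 0.14, those at 24 and 168 h with r = 0.02 and rho = -0.11, and those at 48 and 168 h with r = 0.10 and rho = 0.08. Probe sets are not independent replicates, and 23, 90 and 41 of 100 relabellings lay as far from 0. The r of 24 and 168 h was 0.25 without DA 24 h replicate 1. It turned negative without control 24 h replicate 2 (-0.03), DA 24 h replicate 2 (-0.09), DA 24 h replicate 3 (-0.09), control 168 h replicate 3 (-0.10), DA 168 h replicate 2 (-0.05) or DA 168 h replicate 3 (-0.04). That of 48 and 168 h was -0.04 without control 168 h replicate 3, -0.02 without DA 168 h replicate 3 and -0.00 without control 48 h replicate 2, and 0.21 without control 48 h replicate 1.

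Vehicle-injected fish also differed between collection times. The glucocorticoid targets fkbp5 and klf9 rose, fkbp5 from a mean of 8.01 at 24 h to 10.57 at 48 h and 10.78 at 168 h, and klf9 from 8.91 to 10.67 and 11.23 (adjusted p = 0.0240 and 0.0352, limma F test). The sterol synthesis gene hmgcs1 was higher at 168 h than at 24 h by 1.48 (SE 0.19) and the sterol sensor gene insig1 by 1.08 (SE 0.18). The transcription factor genes klf11a rose by 1.14 (SE 0.13), foxg1b by 1.81 (SE 0.24) and sox11b by 1.04 (SE 0.17), the chaperone hsp90aa1.2 by 1.04 (SE 0.14) and the clock-linked gene nfil3-5 by 1.75 (SE 0.31). sox9b, the clathrin heavy chain gene cltcb and lhx9 fell, with differences of -0.78, -0.76 and -0.73. These genes were picked from those that passed after their values were seen. Over the 3 control groups, 62 probe sets passed, with 1813 at an unadjusted p under 0.05, and 168 h against 24 h gave 69, of which 47 were higher. Collection time cannot be told apart from any array run that went with it, and spike-ins were highest on the 24 h controls. The count of 62 was 280 without DA 24 h replicate 1, 32 without control 24 h replicate 2, 20 without control 24 h replicate 3 and 6 without control 48 h replicate 1. It was 37 without DA 48 h replicate 1, 34 without DA 48 h replicate 2, 6 without control 168 h replicate 1, 0 without control 168 h replicate 2, 8 without control 168 h replicate 3 and 37 without DA 168 h replicate 2.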

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

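The oxygen-responsive, photoreceptor and lens lists were written, and the tests on short labelled RNA, on the hybridisation run of control 48 h replicate 1, on carried-over photoreceptor and lens tissue, with the blank level as a covariate, and the list tests between times with their alternatives were chosen, only after the result was seen.

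The difference of the DA effect between times was tested for each of 33 lists over 3 pairs of times, and 15 of 99 tests passed with the preset correlation and 0 with an estimated correlation. From 24 to 48 h the median difference of the members' changes was 0.33 for oxidative phosphorylation, 0.28 for ribosomal proteins, 0.22 for oxidative stress and Nrf2 targets and 0.20 for microglia and leukocyte markers (0.199). It was -0.21 for retina, lens and pineal markers, -0.20 for glucocorticoid and handling stress genes and -0.19 for erythroid markers. From 24 to 168 h it was 0.17 for ribosomal proteins, 0.13 for oxidative phosphorylation and -0.35 for retina, lens and pineal markers. From 48 to 168 h it was -0.26 for neuropeptides, -0.22 for oxidative phosphorylation, -0.21 for proteasome subunits, -0.19 for microglia and leukocyte markers and -0.10 for ribosomal proteins. With each array left out, 3 of the 15 calls were kept, those on oxidative phosphorylation and ribosomal proteins from 24 to 48 h and on neuropeptides from 48 to 168 h, while 12 were lost without at least 1 array (adjusted p without it in brackets). From 24 to 48 h the call on erythroid markers was lost without control 24 h replicate 2 (0.135), control 24 h replicate 3 (0.0948), DA 24 h replicate 1 (0.25), DA 24 h replicate 2 (0.0545), control 48 h replicate 2 (0.0906), DA 48 h replicate 1 (0.0689) or DA 48 h replicate 2 (0.0845). Glucocorticoid genes lost theirs without DA 24 h replicate 2 (0.0545), DA 24 h replicate 3 (0.0582) or control 48 h replicate 1 (0.0519). Microglia and leukocyte markers lost theirs without control 24 h replicate 3 (0.0544), DA 24 h replicate 2 (0.0522), DA 24 h replicate 3 (0.0710), control 48 h replicate 1 (0.136) or DA 48 h replicate 2 (0.0787). The oxidative stress genes lost theirs without control 24 h replicate 1 (0.247), DA 24 h replicate 1 (0.135), DA 24 h replicate 2 (0.0545), DA 24 h replicate 3 (0.0978), control 48 h replicate 1 (0.411), DA 48 h replicate 1 (0.0689), DA 48 h replicate 2 (0.0758), control 168 h replicate 2 (0.0512), DA 168 h replicate 1 (0.0564) or DA 168 h replicate 3 (0.0508). Retina, lens and pineal markers lost theirs without DA 24 h replicate 1 (0.780). From 24 to 168 h the call on ribosomal proteins was lost without DA 24 h replicate 3 (0.0827). Oxidative phosphorylation lost its call without control 24 h replicate 1 (0.194), DA 24 h replicate 3 (0.234) or control 168 h replicate 3 (0.267). Retina, lens and pineal markers lost theirs without DA 24 h replicate 1 (0.0821). From 48 to 168 h the call on ribosomal proteins was lost without DA 24 h replicate 1 (0.103), DA 24 h replicate 2 (0.0522), DA 24 h replicate 3 (0.0514), control 48 h replicate 1 (0.570), DA 48 h replicate 1 (0.0634), DA 48 h replicate 2 (0.210), control 168 h replicate 1 (0.407), DA 168 h replicate 2 (0.291) or DA 168 h replicate 3 (0.215). Microglia and leukocyte markers lost theirs without control 24 h replicate 3 (0.0544), DA 24 h replicate 2 (0.0522), DA 24 h replicate 3 (0.0514), control 48 h replicate 1 (0.292), DA 48 h replicate 2 (0.187), control 168 h replicate 1 (0.0763), control 168 h replicate 2 (0.0516), DA 168 h replicate 1 (0.189) or DA 168 h replicate 2 (0.0798). Oxidative phosphorylation lost its call without control 48 h replicate 1 (0.174). Proteasome subunits lost theirs without control 48 h replicate 2 (0.0816), control 168 h replicate 2 (0.170) or DA 168 h replicate 1 (0.0511). The differences of -0.21 and -0.35 for retina, lens and pineal markers thus rested on DA 24 h replicate 1, and were -0.02 and -0.15 without it, where the DA effect at 24 h itself went from 0.17 to -0.05. That of ribosomal proteins from 48 to 168 h turned to 0.02 without control 48 h replicate 1.

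Covariates also ended calls between times. With the spike-in level the adjusted p was 0.0788 for ribosomal proteins and 0.149 for oxidative phosphorylation from 24 to 168 h, and 0.0600 for neuropeptides and 0.325 for microglia and leukocyte markers from 48 to 168 h. With the GAPDH difference it was 0.121 for erythroid markers from 24 to 48 h, and 0.184 for ribosomal proteins and 0.145 for proteasome subunits from 48 to 168 h. With the blank level it was 0.224 for erythroid markers, 0.309 for oxidative stress and 0.70 for retina, lens and pineal markers from 24 to 48 h, 0.725 for the latter from 24 to 168 h, and 0.120 for ribosomal proteins and 0.0587 for microglia and leukocyte markers from 48 to 168 h. The blank tag probe sets, which the comparisons do not use, averaged 5.74 on DA 24 h replicate 1, above all control arrays.

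Without DA 24 h replicate 1, fkbp5 and tial1 rose and chd2, kdm4b and atrx fell at 24 h, among 217 probe sets. With control 24 h replicate 3 left out as well, 237 probe sets passed. A count of this size thus does not need the short labelled RNA of that array. Whether these are the same probe sets was not examined, so the short RNA stays open for single genes. The hybridisation run stays open, since controls and DA replicates 2 and 3 differed in spike-in level by -0.96, and DA replicate 1, nearer to the other DA arrays for 53 of the 217, had a level of 10.56, within the controls' range of 10.39 to 10.96. Slopes on that level, taken within groups over 11 arrays of 48 and 168 h, predicted the direction of 60.8% of the 217, from 35.0% to 83.9% with each array left out, against 52.9% of all probe sets. With the spike-in covariate 3 probe sets passed because the SE rose from 0.15 to 0.21 while the median change went from 0.75 to 0.71, so run and toxin cannot be told apart for these genes, and a response of unequal size between DA pools, which may also be the source, was not tested.

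Of 31 genes known to respond to oxygen, 5 that prompted the list, among them egln3 and cox4i1l, were lower in DA fish at 48 h with a median of -0.82, and the 26 not looked at before had a median of -0.07 with 16 lower (camera in limma, p = 0.0159, and p = 0.0974 with an estimated correlation). The hybridisation run of control 48 h replicate 1 stays open, since control 48 h replicate 2 lay above every 48 h DA array for 5 of the 5 genes first looked at, but these were picked for that difference and its spike-in level was also above those of the DA arrays. On the 26 members, the 48 h controls were higher than the other controls (camera p = 0.00295, p = 0.0472 with an estimated correlation, 17 of 26 higher, median 0.14). For the same members, the 48 h DA arrays against the other DA arrays gave a median of 0.07, with 15 of 26 higher. The camera p was 0.984 in limma, which by itself neither shows nor excludes a lowered level there. The difference may therefore lie in the 48 h control pools, for example from lower oxygen before those fish were collected, a candidate that the labels do not allow to be tested.

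Photoreceptor genes were lower in DA fish at 168 h in 23 of 23 genes, the brightest being pde6ha (mean 7.59 in DA, 8.86 in controls) and rbp4l (7.46 and 8.70), and all 23, like the 9 lens genes, are also in the retina, lens and pineal list. A general shift of dim probe sets stays open, since their median of -0.23 lay below the range of -0.08 to 0.02 that holds the middle of 1000 random sets of like level, but the blank level, which that bound leaves out, differed by -0.12, and with it as a covariate the call on the wider list ended (adjusted p = 0.234) as the 23 genes' median shrank to -0.10 (median SE 0.13, from 0.24), or to -0.17 without DA 24 h replicate 1. Photoreceptor tissue carried into some pools may be the source. The test used the 10 arrays outside 168 h other than DA 24 h replicate 1, left out for its bright blank probe sets. There these genes rose and fell together within groups (mean pairwise r = 0.436, against 0.151 at the upper 5% of random sets). A shared change in their expression would also give this, so the test cannot tell it from carried-over tissue. The lens crystallins, at a mean level of 5.26, were lower in 9 of 9 with a median of -0.125 (SE 0.03), just past both -0.113 and -0.118, the bounds asked of them, but lens tissue stays open, since within groups over the 11 arrays outside 168 h lens and photoreceptor means gave r = 0.805 and rho = 0.582 (exact permutation p = 0.153 and 0.197, adjusted over 4 tests 0.394), r = 0.498 without the 2 farthest arrays, and r = 0.0822 and rho = -0.0303 (p = 0.882 and 0.951, adjusted 0.951) without DA 24 h replicate 1, the highest in both. A change in the pineal or in the fish's own photoreceptor expression stays open as untested. The pineal opsin gene exorh was highest on DA 48 h replicate 3 (7.18) and control 168 h replicate 3 (7.10). gngt1 was also highest there, at 7.13 and 7.47. On control 48 h replicate 1, where pde6ha was at 10.34, exorh was at 6.40.

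The counts were set against other splits of the same arrays, except those at 48 h alone, for which no splits were run. At 24 h the real split gave 5 probe sets and the highest other 99, with as many in 2 of 10 splits, and 10 splits are too few for a share under 0.05. The split with 99 set control replicates 1 and 2 with DA replicate 1 against the rest, which are the 3 arrays of 24 h with the highest spike-in levels, so it points to a structure of the samples, and whether that structure follows the hybridisation run was not tested. As many lists as the 3 at 24 h were found in 9 of 10 splits (highest other 8). As many as the 1 list at 168 h were found in 8 of 10 (highest other 7). Most other splits thus gave as many lists or more, so chance cannot be excluded for these 2 counts. The limit of 10 splits also holds for the 217 probe sets at 24 h without DA replicate 1. There the highest other of 10 splits gave 3 and as many were found in 1. A count of 0 is met by every split, so the comparison says nothing about chance for the 0 probe sets at 168 h (10 of 10 splits, highest other 0), in the mean effect (100 of 100 relabellings, highest other 35) and for the difference between times (100 of 100, highest other 114). For the 1 list in the mean effect chance cannot be excluded (94 of 100, highest other 10). For time in controls 62 probe sets passed, with as many in 3 of 100 splits, real one included, and 93 in the highest other. A share this size makes chance less likely but does not exclude it, and the count was 0 without control 168 h replicate 2.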

How the results depend on the processing

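The spike-in, GAPDH and blank covariates, the removal of both doubted 24 h arrays, array weights for lists and the removal of arrays from the control time test, the correlations and the list tests between times were chosen after seeing the data. The counts at 168 h and for the difference between times were 0 under every alternative run on them, planned or added. The exception was 30 at an unadjusted p and 1.5 fold at 168 h. The other thresholds were not applied to the difference between times. Among the genes named, 3836 values under an alternative kept direction and side, 115 newly passed, 71 no longer passed, 93 changed sign while passing neither before nor after, and 0 changed sign with a call on either side. Signal near background limits the dim probe sets, and leaving these out raised the 24 h count.

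For each change given here the cause was not tested, except where fewer arrays or fewer tests make it plain. The 24 h count of 5 was 32 with median centring, 3 with repeated quantile normalisation, 3 with cyclic loess, 19 above the median level, 23 above the lower quartile, 24 with trend and robust variances, 90 with array weights and 237 without both doubted arrays. It was 0 with the spike-in covariate, 0 with the GAPDH covariate, 327 with the blank covariate, 50 at an adjusted p under 0.10, 297 at an unadjusted p and 1.5 fold and 0 with the 2 groups alone. With each array left out it ran from 0 to 217. The 48 h count of 0 was 1 with array weights, 1 with the spike-in covariate and 117 at an unadjusted p and 1.5 fold, and ran from 0 to 4 with each array left out. The 168 h count ran from 0 to 0 and that for the difference between times from 0 to 0. The mean effect's count of 0 was 5 with median centring, 9 above the median level, 9 above the lower quartile, 9 with trend and robust variances, 209 with array weights (191 lower), 117 without both doubted arrays, 69 with the blank covariate and 11 at an adjusted p under 0.10, and ran from 0 to 163. The count of 62 for time in controls was 24 with median centring, 98 with quantile normalisation, 115 with cyclic loess, 135 with array weights, 333 without both doubted arrays, 26 with the spike-in, 4 with the GAPDH and 255 with the blank covariate, and ran from 0 to 280.

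The 3 lists at 24 h became 0 with an estimated correlation and 0 with fry, and ran from 0 to 5 with each array left out. The 9 lists at 48 h became 5 with the spike-in covariate, 0 with an estimated correlation and 0 with fry, and ran from 2 to 11. The 1 list at 168 h became 3 above the median level, 2 with array weights, 0 with the blank covariate, 0 with an estimated correlation, 2 on ranks, 0 with fry and 2 with the mean over probe sets, and ran from 1 to 4. The 1 list in the mean became 3 above the median level, 5 with array weights, 2 without both doubted arrays, 5 with the spike-in covariate, 4 with the blank covariate, 0 with an estimated correlation and 0 with fry, and ran from 1 to 5. Retina, lens and pineal markers at 24 h turned from higher to lower, at an adjusted p of 0.775 with array weights, 0.344 without DA replicate 1, 0.914 without both doubted arrays and 0.137 with the blank covariate, and ran from 2.90e-06 to 0.344 with each array left out. With the blank covariate their change between times turned sign, at an adjusted p of 0.700 from 24 to 48 h and 0.725 from 24 to 168 h. That of ribosomal proteins from 48 to 168 h ran from 3.90e-06 to 0.570 with each array left out and turned without control 48 h replicate 1. The correlations ran from 0.0999 to 0.201 (24 and 48 h), -0.0994 to 0.255 (24 and 168 h) and -0.0396 to 0.208 (48 and 168 h).

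With the replicate number within time as a block, the 24 h count was 0, those at 48 h, at 168 h, in the mean and between times were 0, and the lists numbered 3 at 24 h, 11 at 48 h, 1 at 168 h and 4 in the mean. For time in controls the block was not run, since it is not estimable there. Deviations of DA and control arrays with the same number correlated across probe sets with r from -0.33 to 0.22, so the numbers gave no sign of pairing.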

Other observations

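The list tests on time in control fish, the score over the genes of the 24 h comparison and the values named here were chosen after seeing the data.

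In vehicle-injected fish, genes of sterol synthesis were higher at 168 h than at 24 h in 11 of 12 members, with a median of 0.25 on the log2 scale (adjusted p = 6.24e-06, and adjusted p = 0.0496 with an estimated correlation). hmgcs1, which makes the precursor of mevalonate, went from a mean of 8.10 to 9.57 and the sterol sensor gene insig1 from 9.01 to 10.08. The DA fish showed the same direction, with hmgcs1 at 8.11 and 9.81, insig1 at 8.93 and 10.27 and a list median of 0.41, all over the full set of DA arrays. With DA 24 h replicate 1 left out, camera in limma gave an unadjusted p of 3.22e-11, higher. Glucocorticoid-responsive genes were higher in 13 of 20 members (adjusted p = 0.00114, and adjusted p = 0.0655 with an estimated correlation). In DA fish fkbp5 went from 9.42 to 10.83 and klf9 from 9.73 to 11.25. Of the 47 genes that passed the F test of time in controls, 44 had the same sign in the DA arrays, 168 h minus 24 h. That count takes sign alone, and the share over all genes was not computed. Some of the 47 showed little difference between these times in controls, such as selenom at 0.09 (adjusted p = 0.842, limma). The control falls named earlier were smaller or absent in DA fish, with sox9b at -0.02, cltcb at -0.23 and lhx9 at 0.04. In controls these genes were at -0.78, -0.76 and -0.73. The control rises named earlier ran in DA fish from 0.65 (sox11b) to 1.71 (hmgcs1).

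Other groups also differed between 168 and 24 h in controls with the preset correlation. The unfolded protein response was higher in 20 of 30 genes (adjusted p = 0.00289, and adjusted p = 0.401 with an estimated correlation) and immediate early genes in 28 of 36 (adjusted p = 0.00668, and adjusted p = 0.609 with an estimated correlation). Estrogen-responsive genes were higher in 8 of 10 (adjusted p = 0.0381, and adjusted p = 0.232 with an estimated correlation) and heat shock genes in 25 of 39 (adjusted p = 0.0381, and adjusted p = 0.434 with an estimated correlation). Ribosomal proteins were lower in 55 of 71 (adjusted p = 1.81e-07, and adjusted p = 0.609 with an estimated correlation) and oxidative phosphorylation in 57 of 84 (adjusted p = 0.00114, and adjusted p = 0.723 with an estimated correlation). In DA fish without DA 24 h replicate 1, oxidative phosphorylation was higher at 168 h than at 24 h (unadjusted camera p in limma 0.000785, and p = 0.435 with an estimated correlation), while its median over all DA arrays was 0.03. Ribosomal proteins did not pass there (unadjusted camera p in limma of 0.209), and their median over all DA arrays was -0.00. Synaptic vesicle and neuronal genes were lower in 12 of 20 (adjusted p = 0.0120, and adjusted p = 0.609 with an estimated correlation).

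A score per array was taken as the mean of the 96 probe sets that rose minus the mean of the 121 that fell at 24 h without DA replicate 1. At 24 h it was -0.75 to -0.71 on the control arrays, -0.41 on DA replicate 1, and 0.94 and 0.96 on DA replicates 2 and 3. These 5 arrays other than DA replicate 1 defined the score, so their values are no test of it. The other arrays entered through the shared estimate of spread, so they are not independent of the choice either. At 168 h the score was 0.43 and 0.45 on DA replicates 2 and 3 and -0.21 on DA replicate 1, against 0.02, 0.03 and -0.20 on the controls. chd2, which fell at 24 h, was at 7.46 on DA 168 h replicate 2 and 8.86 on DA 168 h replicate 1. At 48 h the score was 0.14, 0.05 and 0.03 on the DA arrays and 0.08 and -0.13 on the controls. Over the 11 arrays of 48 and 168 h, the score and the spike-in level gave r = -0.24 (permutation p = 0.469, adjusted over the 2 measures 0.469) and rho = -0.49 (permutation p = 0.130, adjusted 0.259). The permutations ran over all 11 arrays without regard to group. These p therefore mix treatment and time with the hybridisation run and decide nothing about the run. Without the 2 arrays farthest from the median spike-in level, r was -0.35, and within the 6 arrays of 168 h it was -0.67.

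Photoreceptor transcripts varied between single pools at every time. pde6ha was at 11.20 on DA 24 h replicate 1, 10.34 on control 48 h replicate 1 and 9.32 on DA 48 h replicate 3, where the same group's other arrays were at 7.92 and 8.04. gngt1 was at 7.13 on DA 48 h replicate 3 and at 7.47 on control 168 h replicate 3.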
